A study of Mus musculus with 28 samples.

How the data were processed

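The series measured mouse P19 embryonal carcinoma cells, an established pluripotent line, as they became neural cells in retinoic acid. Per the labels' protocols, the cells received 1 µM retinoic acid for 4 days to give neural stem and progenitor cells, and were then replated in neuronal medium until day 8. In a second arm, 1 µL of a 10 mM stock of MS-275, an inhibitor of the class I histone deacetylases, or 1 µL of its solvent DMSO was added on day 1 of retinoic acid, and the cells were collected on day 2. There were 28 samples. RNA-seq covered 10 libraries, 2 each at day 0, day 2 with DMSO, day 2 with MS-275, day 4 and day 8. Native ChIP-seq covered H3K9ac, H3K9cr (crotonylated lysine 9) and H3K18la (lactylated lysine 18), with 2 libraries per mark at day 4 and 1 library per mark and condition at day 2. ATAC-seq, which marks open chromatin, covered 2 libraries at day 4. The 4 input libraries had no processed file used here. The series describes its replicates as biological; how far apart the cultures were grown is not given in the sources used here.

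The RNA file held estimated counts per gene, which the authors made with Salmon 1.1.0, per the submitters' processing notes, with no scaling between libraries. How transcripts were summed to genes, and with which annotation release, was not given in the sources used here. Between 19.2% and 25.8% of the values of a library were not whole numbers, so the estimated counts as deposited were rounded before testing. The processing notes also name DESeq2 1.26.0; its results were not used here. The table held 55385 gene identifiers, of which 55144 were matched to a symbol.

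The peak files held 14 lists, 1 per library, per the file headers, which carry the column names of MACS2 tables. The submitters' processing notes name Bowtie2 2.4.1, MACS2 2.2.7.1 and GRCm38. Each deposited list gave a position, the pileup signal at the summit, the −log10 p-value and −log10 q-value of the authors' caller, and its fold enrichment, a ratio over the local background. The lowest −log10 q-value of a deposited list lay between 2.00 and 2.02. Caller settings and the control used were not given in the sources used here. The fold enrichment is the authors' value. It was used to rank and describe peaks within a list. It was also used to correlate peak strength with CPM across genes, with 0 for genes without a peak. Its medians and maxima are given per list without a test between lists. Peak lists give no read depth, so the depth of the ChIP and ATAC libraries is unknown here.

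Total estimated counts ranged from 18115738 to 19586107 per RNA library. CPM, the rounded counts scaled to library size with TMM factors, were computed per gene, and errors are standard deviations (SD) over 2 libraries. Gene tests used edgeR 4.0.16: filterByExpr kept 17789 genes, and 1 quasi-likelihood fit over all 10 libraries shared the spread between the 5 groups. The comparisons were day 4 against day 0, day 8 against day 4, and MS-275 against DMSO at day 2. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Standard errors of log2 fold changes were taken from the size of the fold change and the F statistic. Against a group with no counts, a fold is a lower bound against a floor of 3 counts over the group. Against a group with 1 to 3 counts, the ratio is printed with its 95% counting interval. Intervals and floors cover counting error only. Other genes whose fitted fold moved by more than 1.5 times when 1 library was left out are given by their CPM without a fold.

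Gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The 22 lists were pluripotency; neural stem and progenitor; neuron; astrocyte and oligodendrocyte; retinoic acid response; Hox paralogs 1 to 5; Hox paralogs 9 to 13; primitive streak and endoderm; cardiac and muscle; fibroblast and mesenchyme; neural crest; glycolysis and lactate; oxidative phosphorylation; histone acylation writers, erasers and readers; crotonyl-CoA and acyl-CoA supply; DNA replication; mitosis; CDK inhibitors and p53 targets; germline and meiosis; Notch pathway; stress and immediate early; and synapse and ion channel. Lists were tested with camera in limma 3.58.1 on voom log2 CPM, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists of a comparison. Each test was also run with the correlation estimated per list, adjusted in the same way. Camera sets the members of a list against all other tested genes.

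Genes were named by rule: per comparison, the 5 largest rises and the 5 largest falls among called genes with at least a 2-fold change, a mean of at least 5 CPM and groups that did not overlap, leaving out predicted genes, mitochondrial genes and pseudogenes. From each list the rule took the 3 called members with the largest change and a mean of at least 1 CPM, and the largest called change the other way. A panel of 18 genes was followed in every comparison. For each mark, the rule took the 3 gained and 3 lost gene ends with the largest fold enrichment in the authors' list. Genes outside the rule are said to be so where they appear, and 2 genes that the rule took are not reported here.

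Gene positions came from a RefSeq table of GRCm38 that gives no strand. A peak was therefore assigned to a gene when it lay within 1 kb of either annotated end of a protein-coding gene, so the start and the end of a gene were not told apart. Positions were available for 21887 protein-coding genes, of which 20929 were in the RNA table and 14603 were tested. Peaks overlapped when they shared at least 1 bp. Regions present in both day 4 replicates are called reproducible. Overlap was set against the mean of 20 seeded random placements of the peaks on their own chromosomes (5 for day 2), with chromosome lengths taken as the largest coordinate seen in any list. Peaks of DMSO and MS-275 libraries were compared by overlap alone, since there was 1 library per condition. Wilson intervals at 95% are given for shares of peaks lost. Fisher's exact test (two-sided) compared the share of genes with a reproducible region at a gene end between called and uncalled genes, with adjustment over 16 tests.

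Alternatives were size factors in place of TMM, DESeq2 1.42.0 in place of edgeR, no filter on low counts, only the 4 libraries compared, the replicate number as a block, a 2-fold minimum, and leaving out each library in turn with the spread shared across groups. For peaks they were a −log10 q-value of at least 10, an overlap of 50% of the peak, a window of 2.5 kb, lists of equal length, Mantel-Haenszel odds ratios within deciles of day 4 expression, a background of the same DMSO expression range, and each replicate alone. 1 alternative was chosen after seeing the data: for gene sets in the MS-275 comparison, the median change of genes outside the set at the same DMSO level, in 20 bins of equal size, was taken off before camera. It was run for sets taken from the day comparisons and from gained or lost peaks, and not for the gene lists.

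The gene test was tested on simulated data, with counts drawn for the real genes at the real library sizes and 200 changed genes per comparison. The changed genes were drawn only from well-counted genes, and the spread followed its trend over expression rather than each gene's own value. Recovery therefore does not cover low genes, and far fewer genes changed than were called in the data. In the comparison of day 4 with day 0 (17415 simulated genes), 94.0% of 1.5-fold, 95.5% of 2-fold and 100% of 4-fold changes were recovered, with 2.53% of calls false. In that of day 8 with day 4 (17462 genes) these shares were 80.6%, 98.5% and 100%, with 4.62% of calls false. In that of MS-275 with DMSO (17412 genes) they were 79.1%, 97.0% and 100%, with 5.15% of calls false. Camera found the set of 30 raised genes in each simulated comparison, and the set of 30 unchanged genes in none of them. The raised set was taken from the genes changed by design. Counts were drawn independently for each gene, so camera's preset correlation was not checked by this. The peak overlap functions passed 4 checks on simulated intervals. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.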

Results

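RNA-seq followed P19 cells through neural differentiation at day 0, day 4 and day 8, and compared MS-275 with DMSO at day 2, with 2 libraries in each of the 5 groups. Total estimated counts lay between 18115738 and 19586107 per library. Genes with at least 10 counts numbered 15166 ± 74.2 at day 0, 14940 ± 77.8 with DMSO, 16472 ± 29.7 with MS-275, 15408 ± 58.7 at day 4 and 15862 ± 38.2 at day 8 (SD, n = 2). The first principal component held 51.0% of the variance and ran from day 0 (−129 and −129.6 for the libraries) through the day 2 groups to day 4 (102 and 100.2) and day 8 (112 and 107). Replicates correlated across genes with Pearson values of 0.996 to 0.997; genes are not independent replicates. Replicates differed by more than counting error in every group, by a chi-square over degrees of freedom of 2.82 at day 0, 2.91 with DMSO, 3.58 at day 4, 5.31 with MS-275 and 6.28 at day 8. The p-values of edgeR gene tests measure the spread between these libraries. Camera p-values set gene statistics inside a list against those outside it, so with the preset correlation they also rest on the number of genes. Fisher's exact and Mantel-Haenszel tests count genes as units. Every RNA level below is a mean CPM ± SD over 2 libraries.

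The comparison of day 4 with day 0 asked which genes changed as pluripotent P19 cells became neural stem and progenitor cells. Pou5f1, which encodes a core pluripotency factor (chromosome 17, 35506032 to 35510777), had 2.65 ± 0.488 CPM at day 4 and 1418 ± 22.9 at day 0 (SD, n = 2), a 535-fold fall (log2 fold change −9.06, SE 0.0939, edgeR adjusted p = 3.49e-19). Hox genes, which set position along the body axis, went from no counts at day 0 to high levels: Hoxb3 (chromosome 11, 96307101 to 96347930) reached 698 ± 14.5 CPM, at least 8577-fold higher, Hoxb6 398 ± 8.68 (at least 4889-fold) and Hoxb5 383 ± 6.10 (at least 4707-fold). The proneural factor Neurog1 reached 106 ± 12.9 CPM and the neural plate factor Pax3 185 ± 6.55, both from no counts (at least 1300-fold and 2281-fold higher). The microtubule protein Dcx of young neurons (chromosome X, 143855842 to 143933396) rose from 0.753 ± 0.272 to 474 ± 31.7 CPM, 618-fold (log2 9.27, SE 0.116, adjusted p = 9.36e-19), and the axon guidance receptor Dcc rose from 0 to 349 ± 22.3 (at least 4296-fold). The neuronal factor Nhlh2 was at least 3011-fold higher, the epithelial splicing regulator Esrp1 (chromosome 4, 11331933 to 11386783) fell from 25.5 ± 1.87 CPM to 0 (at least 315-fold), and Cyp2b23 from 113 ± 2.04 CPM to 2 counts (ratio 2085, 95% counting interval 577 to 17220).

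Of 23 tested pluripotency genes, 20 fell, 2 rose and 1 was not called (median log2 −6.47, −6.35 with genes at 0 counts set to their bound). L1td1 fell 1490-fold, from 452 ± 19.07 to 0.298 ± 0.0501 CPM, Utf1 went from 324 to 0.159 CPM, Nanog from 9.20 to 0.741, and Dppa4 fell at least 314-fold; Klf4 rose 3.20-fold and Sox2, shared with neural progenitors, 1.40-fold. Of 29 neural stem and progenitor genes, 28 rose and Sox3 fell 1.69-fold (median log2 4.31); Sox1 rose 45.5-fold and Pax6 went from 2.33 to 46.0 CPM. All 15 Hox paralogs 1 to 5 rose (median log2 12.39, 9.89 at the bounds). These 3 lists stood apart from other genes by camera (adjusted p = 5.01e-06, 3.37e-11 and 1.89e-06), each also with an estimated correlation (adjusted p = 0.0339 for each).

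Other neural lists rose too. Of 32 neuron genes, 29 rose and 2 fell (median log2 3.40, camera adjusted p = 1.08e-10; adjusted p = 0.116 with an estimated correlation): the tubulin Tubb3 rose 10.5-fold to 734 ± 5.40 CPM and the dendrite protein Map2 39.3-fold to 728 ± 16.8, while the neurofilament Nefh fell 10.0-fold. Of 33 synapse and ion channel genes, 27 rose and 6 fell (median log2 2.14, adjusted p = 4.34e-06; 0.0505 with an estimated correlation); the glutamate receptor subunit Gria2 rose 372-fold. Of 20 Notch pathway genes, 15 rose and 2 fell (median log2 1.96, adjusted p = 0.000514; 0.0641 with an estimated correlation), among them the Notch target Nrarp, 49.5-fold. Of 20 retinoic acid response genes, 14 rose and 3 fell (median log2 2.92, adjusted p = 0.00109; 0.159 with an estimated correlation). In that list Nr2f1 rose 900-fold, the retinoic acid hydroxylase Cyp26b1 reached 129 ± 25.5 CPM against 1 count (ratio 4732, 95% counting interval 849 to 186920), and the receptor Rarg fell 20.9-fold.

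Markers of other lineages moved with the neural genes. Of 18 fibroblast and mesenchyme genes, 14 rose and 3 fell (median log2 2.28, camera adjusted p = 0.00296; 0.254 with an estimated correlation), with Col3a1 up 202-fold to 466 ± 41.9 CPM and Tagln down 24.8-fold. Of 15 neural crest genes, 11 rose and 3 fell (median log2 3.36, 3.31 at the bounds, adjusted p = 0.0155; 0.159 with an estimated correlation); Ednrb rose 102-fold and Foxd3 fell 9.13-fold. Mitosis genes fell in 16 of 24 cases and rose in 2 (median log2 −0.42, adjusted p = 0.00116; 0.474 with an estimated correlation), among them Bub1, 2.44-fold, and Cdc20, 2.26-fold.

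The remaining lists were not called at day 4. Hox paralogs 9 to 13 had 5 rises and 3 falls among 9 tested genes (median log2 5.96, 3.20 at the bounds, adjusted p = 0.290), with Hoxa9 at least 244-fold higher and Hoxb9 going from 1.02 to 1317 CPM. Astrocyte and oligodendrocyte genes split into 8 rises and 8 falls of 19 (0.659), with Sox9 up 69.1-fold. Primitive streak and endoderm genes had 8 rises and 6 falls of 17 (0.858), cardiac and muscle genes 3 and 9 of 15 (0.273), and germline and meiosis genes 0 and 5 of 11 (0.250). Glycolysis and lactate genes had 4 rises and 12 falls of 23 (0.287): the glucose transporter Slc2a3 fell 8.58-fold to 154 ± 19.6 CPM, and Ldha, which encodes lactate dehydrogenase A, had 589 ± 51.7 CPM at day 4 and 488 ± 14.0 at day 0 (edgeR adjusted p = 0.272). Ldha was called higher without a filter on low counts and with only the 4 libraries compared (log2 0.28 in each). Histone acylation writers, erasers and readers split into 14 rises and 14 falls of 34 (0.858), with the crotonyl-lysine reader Mllt3 up 19.6-fold, the deacylase Sirt1 down 4.95-fold and the crotonyl-CoA hydratase Cdyl down 4.18-fold. Crotonyl-CoA and acyl-CoA supply had 8 rises and 7 falls of 18 (0.749), with Hmgcs1 up 7.48-fold and Acly up 3.21-fold. DNA replication had 8 rises and 14 falls of 25 (0.290). Oxidative phosphorylation had 9 and 9 of 24 (0.858; median log2 −0.08, mean 0.12), CDK inhibitors and p53 targets 9 and 10 of 23 (0.858; median 0.01, the test pointing down), and stress and immediate early genes 11 and 8 of 21 (0.927; median 0.27, mean −0.02), where the stress pseudokinase Trib3 fell 31.5-fold.

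In all, 12866 of 17789 genes were called between day 4 and day 0 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6446 higher and 6420 lower; 3681 were at least 2-fold higher and 3229 at least 2-fold lower. The 2 groups did not overlap for 85.7% of genes, where chance gives 33.3%. Adjusted over the list alone, the counts were the same for every list except DNA replication (9 higher, 15 lower). Retinoic acid and time in culture changed together between these days. The Hoxb3 locus contains Hoxb4 and overlaps an antisense gene, as do Hoxb5 and Hoxb6, so reads from these neighbours may be shared between them.

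**Figure D1:**
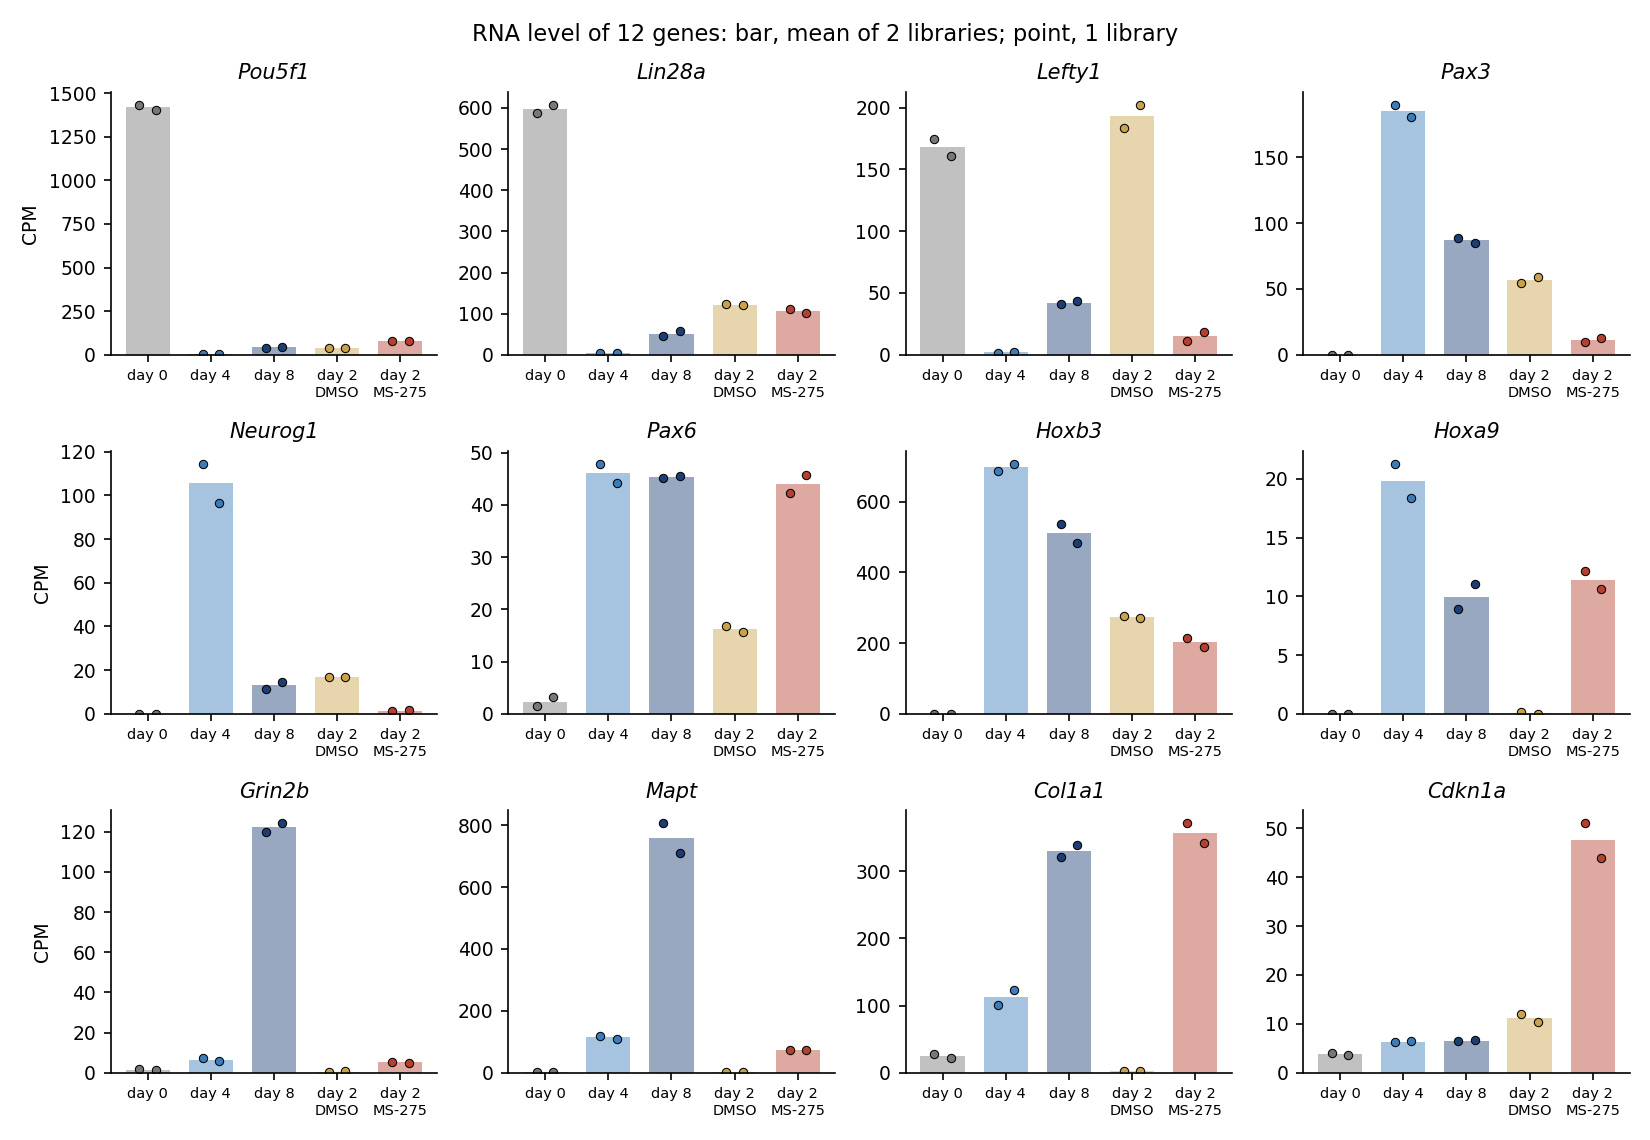
Bars give the mean CPM of 2 RNA libraries in each of the 5 groups, and points give each library, for 12 genes on linear axes from 0. Pou5f1 stood at 1418 CPM at day 0 and 2.65 at day 4, Hoxb3 was at 0 at day 0 and 698 at day 4, and Col1a1 stood at 3.33 with DMSO and 357 with MS-275.

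The comparison of day 8 with day 4 asked what changed as progenitors were replated and became neurons. Receptors and proteins of mature neurons rose: the metabotropic glutamate receptor Grm5 (chromosome 7, 87583981 to 88135063) went from 0.485 ± 0.0570 to 44.3 ± 0.0443 CPM (SD, n = 2), 90.0-fold (log2 6.49, SE 0.209, edgeR adjusted p = 1.10e-12). The NMDA receptor subunit Grin2b rose 18.6-fold to 122 ± 3.34 CPM, Grin1 17.4-fold to 31.5 ± 3.56, and the axonal microtubule protein Mapt (chromosome 11, 104229409 to 104332090) 6.64-fold, from 114 ± 5.28 to 759 ± 70.5 CPM. Cyp26b1 and Cyp26a1, whose products break down retinoic acid, fell 38.4-fold to 3.35 ± 0.386 CPM and 14.6-fold to 2.43 ± 0.661. The pluripotency gene Pou5f1 rose 15.7-fold to 41.8 ± 3.28 CPM (log2 3.98, SE 0.108, adjusted p = 2.29e-13), which was 2.94% of its day 0 level. Lefty1, an inhibitor of Nodal signalling, rose 22.2-fold to 42.1 ± 1.43 CPM, 25.1% of its day 0 level. Other large rises were those of Ablim3 (51.7-fold), the brain proteoglycan Bcan (48.5-fold) and the steroidogenic factor Nr5a1 (31.3-fold), with Kndc1 going from 0.290 to 10.2 CPM, and the Wnt target Sp5 fell 21.2-fold. The immediate early gene Fosb (chromosome 7, 19302696 to 19310118) went from 142 ± 6.76 to 3.48 ± 3.49 CPM and Dmrta1 from 10.2 to 0.631.

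Of 33 synapse and ion channel genes, 31 rose and none fell (median log2 1.31, camera adjusted p = 1.17e-21; 0.00940 with an estimated correlation). Of 32 neuron genes, 21 rose and 8 fell (median log2 0.46, adjusted p = 0.000155; 0.259 with an estimated correlation): the vesicular glutamate transporter Slc17a6 rose 6.45-fold and the motor neuron factor Isl1 fell 8.31-fold, while Tubb3 had 777 ± 104 CPM at day 8 and 734 ± 5.40 at day 4 (edgeR adjusted p = 0.403). Of 29 neural stem and progenitor genes, 16 fell and 8 rose (median log2 −0.29, adjusted p = 0.00495; 0.203 with an estimated correlation). Neurog1 fell 8.14-fold to 12.97 ± 2.11 CPM and Zic2 3.36-fold, whereas Pax6 had 45.3 CPM at day 8 and 46.0 at day 4 and was not called. Without day 8 replicate 1 Tubb3 was at log2 −0.07, and without replicate 2 it was called higher at 0.20. Mitosis genes fell in 22 of 24 cases and none rose (median log2 −0.35, adjusted p = 1.06e-07; 0.233 with an estimated correlation), with Top2a 1.67-fold lower. DNA replication genes fell in 15 of 25 cases and Orc1 rose (median log2 −0.20, adjusted p = 2.35e-05; 0.203 with an estimated correlation); the Orc1 rise was lost without day 4 replicate 1 (log2 0.34) or day 8 replicate 2 (0.23). Notch pathway genes fell in 13 of 20 cases and rose in 5 (median log2 −0.46, adjusted p = 0.00238; 0.109 with an estimated correlation), with the ligand Dll1 2.25-fold lower.

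Of 23 pluripotency genes, 15 rose, 3 fell and 5 were not called (median log2 2.77, 2.5 at the bounds, camera adjusted p = 0.00291; 0.108 with an estimated correlation). The genes that rose reached 0.517% to 93.2% of their day 0 levels (median 8.56%). The number of rises was 13 when any 1 of the 4 libraries was left out. Nanog went from 0.741 to 7.79 CPM and Nodal from 0.221 to 5.21, while Sox2 fell 1.45-fold. Hox paralogs 1 to 5 fell in 12 of 15 cases and rose in 1 (median log2 −0.69, adjusted p = 1.89e-07; 0.0321 with an estimated correlation), among them Hoxc4, 2.49-fold; the 1 rise, of Hoxa4, was not called without day 4 replicate 1 (log2 0.21), day 4 replicate 2 (0.24) or day 8 replicate 1 (0.16). Neural crest genes fell in 10 of 15 cases and rose in 1 (median log2 −0.74, adjusted p = 0.000155; 0.0797 with an estimated correlation), with Msx1 9.63-fold and Tfap2a 3.96-fold lower. Stress and immediate early genes fell in 16 of 21 cases and rose in 2 (median log2 −1.66, adjusted p = 2.34e-07; 0.108 with an estimated correlation). Fos had 28.5 ± 23.3 CPM at day 8 and 283 ± 21.0 at day 4; its log2 fold change was −4.56 without day 8 replicate 1 and −2.66 without day 8 replicate 2. Glycolysis and lactate genes fell in 16 of 23 cases and rose in 4 (median log2 −0.58, adjusted p = 0.000483; 0.432 with an estimated correlation). Ldha fell 2.52-fold to 234 ± 22.5 CPM, the lactate transporter Slc16a3 3.90-fold and Pdk1 3.25-fold.

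Astrocyte and oligodendrocyte genes rose in 10 of 19 cases and fell in 3 (median log2 0.44, camera adjusted p = 0.0463; 0.194 with an estimated correlation), with Aldh1l1 up 13.1-fold to 24.5 ± 6.94 CPM and Olig2 15.3-fold to 5.88 ± 0.231. That list was not called without day 4 replicate 1 (adjusted p = 0.0533) or day 8 replicate 2 (0.0587). Retinoic acid response genes fell in 9 of 20 cases and rose in 6 (median log2 −0.12, adjusted p = 0.0401; 0.290 with an estimated correlation), and were not called without day 8 replicate 1 (0.0539) or replicate 2 (0.0511). Among lists that were not called, primitive streak and endoderm had 7 rises and 3 falls of 17 (0.532), with Eomes up 19.7-fold to 8.65 ± 1.48 CPM, and cardiac and muscle had 6 and 2 of 15 (0.482), with Ryr2 up 13.6-fold to 23.2 ± 1.23. Fibroblast and mesenchyme had 9 and 7 of 18 (0.611), with Dcn up 6.07-fold and Twist1 down 6.11-fold. Histone acylation genes had 3 rises and 12 falls of 34 (0.173), with Hdac11 up 2.14-fold and Mllt3 down 2.25-fold, and acyl-CoA supply 3 and 6 of 18 (0.416). Hox paralogs 9 to 13 had 2 and 2 of 9 (0.611; median log2 −0.04, mean 0.41), with Hoxb9 2.93-fold lower. Oxidative phosphorylation had 1 and 3 of 24 (0.841; median 0.01, the test pointing down), CDK inhibitors and p53 targets 6 and 6 of 23 (0.423; median 0.03, the test pointing down), and germline and meiosis 1 and 0 of 11 (0.611).

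In all, 7387 genes were called between day 8 and day 4 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3866 higher and 3521 lower; 1646 were at least 2-fold higher and 657 at least 2-fold lower. The groups did not overlap for 67.8% of genes (33.3% by chance). Adjusted over the list alone, counts of rises and falls were 8 and 17 for neural stem and progenitor, 11 and 3 for astrocyte and oligodendrocyte, 3 and 2 for Hox paralogs 9 to 13, 4 and 17 for glycolysis and lactate, 0 and 1 for oxidative phosphorylation, 1 and 19 for DNA replication and 2 and 18 for stress, and unchanged for the other lists. Retinoic acid was given for 4 days, so its end, the medium, the substrate and time changed together between these days. Lefty1 and Lefty2 share sequence, so reads may be split between them.

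MS-275 was compared with DMSO at day 2 to ask how inhibition of class I histone deacetylases alters early differentiation. Genes that were near silent with DMSO appeared with the drug: the protein-arginine deiminase gene Padi2 (chromosome 4, 140906336 to 140952586) had 42.8 ± 5.50 CPM against 2 counts (ratio 785, 95% counting interval 217 to 6491), and the tight junction gene Cldn6 went from 0.354 ± 0.0179 to 54.3 ± 7.71 CPM, 150.4-fold (SD, n = 2). The surface glycoprotein gene Thy1 had 19.7 ± 0.351 CPM against 2 counts (ratio 362, 99.8 to 2991), and Pla2g1b rose 163-fold. The collagen gene Col1a1 (chromosome 11, 94936224 to 94953042) rose 107-fold, from 3.33 ± 0.0400 to 357 ± 21.6 CPM (log2 6.74, SE 0.135, edgeR adjusted p = 2.07e-15), and Mapt 60.8-fold, from 1.20 ± 0.147 to 73.4 ± 0.898. Cdkn1a, which encodes the cell cycle inhibitor p21, rose 4.26-fold from 11.1 ± 1.12 to 47.5 ± 5.13 CPM. The proneural gene Neurog1 fell 11.7-fold, from 16.9 ± 0.167 to 1.44 ± 0.497 CPM. The synaptic adhesion gene Lrrc4 (chromosome 6, 28828126 to 28831747) fell furthest among named genes, 92.9-fold from 53.6 ± 6.39 to 0.571 ± 0.248 CPM (log2 −6.54, SE 0.177, adjusted p = 6.23e-14), ahead of Prdm13 (24.8-fold), Ntng2 (24.1-fold) and Itgb8 (23.1-fold).

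With the drug, neural progenitor genes were lower and genes of several other programmes higher, before any allowance for DMSO level. Of tested genes under 1 CPM with DMSO, 43.9% rose at least 2-fold and 2.57% fell. Of those over 100 CPM, 0.692% rose and 6.99% fell. The lists in this comparison were not tested with the change of genes at the same DMSO level taken off. How much of their change goes with DMSO level is therefore unknown. Only genes past the filter on low counts were tested, among them 9 of 16 Hox paralogs 9 to 13 and 11 of 21 germline and meiosis genes. A gene silent in the other groups passes only through the MS-275 libraries, so the filter favours rises in such lists. Of 29 neural stem and progenitor genes, 19 fell and 9 rose (median log2 −1.09, camera adjusted p = 0.00938; 0.192 with an estimated correlation): Hes5 fell 12.1-fold, Sox21 20.1-fold and Sox1 3.31-fold, whereas Pax6 rose 2.72-fold and Nes 1.75-fold. Notch pathway genes fell in 14 of 20 cases and rose in 3 (median log2 −0.58, adjusted p = 0.00938; 0.148 with an estimated correlation), with Dll4 12.4-fold lower. Hox genes split by position in their clusters: Hox paralogs 1 to 5 fell in 12 of 15 cases and rose in 3 (median log2 −0.57, adjusted p = 0.00442; 0.148 with an estimated correlation), with Hoxc5 11.2-fold and Hoxb5 2.73-fold lower. All 9 tested Hox paralogs 9 to 13 rose (median log2 3.74, adjusted p = 0.00213; 0.148 with an estimated correlation). Hoxa9 (chromosome 6, 52223097 to 52227370) had 11.4 ± 1.08 CPM against 3 counts (ratio 139, 47.3 to 677), and Hoxb13 rose 16.1-fold to 10.6 ± 0.770.

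Of 15 cardiac and muscle genes, 12 rose and 1 fell (median log2 2.51, camera adjusted p = 0.00912; 0.148 with an estimated correlation), with Des up 9.66-fold to 7.94 ± 0.674 CPM. Of 18 fibroblast and mesenchyme genes, 10 rose and 3 fell (median log2 0.53, adjusted p = 0.0370; 0.354 with an estimated correlation; 0.0655 without DMSO replicate 1), with Pdgfrb up 8.42-fold. Of 11 germline and meiosis genes, 8 rose and 1 fell (median log2 2.08, adjusted p = 0.0370; 0.174 with an estimated correlation; 0.0528 without DMSO replicate 1), with Tex19.1 up 61.1-fold. Of 23 pluripotency genes, 16 rose and 7 fell (median log2 1.66, adjusted p = 0.0447; 0.193 with an estimated correlation). That call was lost with size factors in place of TMM (0.0536), without DMSO replicate 1 (0.0696) and without DMSO replicate 2 (0.0596). In this list Dnmt3l rose 25.2-fold to 2.90 ± 0.306 CPM, Utf1 21.6-fold to 8.37 ± 0.216 and Pou5f1 2.03-fold to 79.1 ± 2.98, while Lefty1 fell 12.9-fold and Sox2 2.44-fold. Neuron genes rose in 16 of 32 cases and fell in 7 (median log2 0.50, adjusted p = 0.0370; 0.458 with an estimated correlation; 0.0545 without DMSO replicate 2); Syt1 rose 4.99-fold and Tubb3 fell 1.72-fold. Synapse and ion channel genes rose in 21 of 33 cases and fell in 6 (median log2 0.71, adjusted p = 0.0166; 0.191 with an estimated correlation), with Scn3a 6.16-fold higher and Cplx2 9.77-fold lower.

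CDK inhibitors and p53 targets rose in 16 of 23 cases and fell in 4 (median log2 0.68, camera adjusted p = 0.00912; 0.148 with an estimated correlation): Cdkn2a rose 8.19-fold and the death receptor Fas 13.5-fold, while Cdkn1b fell 2.15-fold. DNA replication genes fell in 21 of 25 cases and rose in 1 (median log2 −0.46, adjusted p = 2.67e-06; 0.168 with an estimated correlation), with Tk1 1.76-fold and Rrm1 1.65-fold lower; the rise, of Orc1, was lost without DMSO replicate 1 (log2 0.26), DMSO replicate 2 (0.18) or MS-275 replicate 1 (0.16). Mitosis genes fell in 17 of 24 cases and rose in 3 (median log2 −0.31, adjusted p = 0.00442; 0.401 with an estimated correlation), with Ube2c 1.94-fold lower. Stress and immediate early genes rose in 13 of 21 cases and fell in 3 (median log2 1.52, adjusted p = 0.0370; 0.373 with an estimated correlation), with Hspb1 up 12.6-fold and Txnip 11.8-fold to 1009.5 ± 77.3 CPM. Oxidative phosphorylation genes fell in 18 of 24 cases and rose in 2 (median log2 −0.25, adjusted p = 0.00350; 0.384 with an estimated correlation), with Ndufs3 1.79-fold lower. Histone acylation writers, erasers and readers fell in 19 of 34 cases and rose in 6 (median log2 −0.23, adjusted p = 0.0319; 0.148 with an estimated correlation). Hdac1, a target of the drug, rose 1.66-fold to 407 ± 13.2 CPM, Hdac2 fell 1.41-fold, and the acyltransferase genes Crebbp and Kat2b fell 2.14-fold and 2.75-fold.

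Lists not called with MS-275 were astrocyte and oligodendrocyte (10 rises, 5 falls of 19; camera adjusted p = 0.163), primitive streak and endoderm (9 and 1 of 17; 0.0913), with Tbxt up 16.1-fold, and neural crest (7 and 6 of 15; 0.647), with Ngfr up 31.5-fold. Retinoic acid response had 9 rises and 9 falls of 20 (0.980; median log2 −0.01, mean 0.69), with Tgm2 up 41.3-fold and Rarb down 2.65-fold. Crotonyl-CoA and acyl-CoA supply had 8 and 7 of 18 (0.855; median −0.03, the test pointing up): Cpt1a rose 13.5-fold, the acetyl-CoA synthetase gene Acss2 2.00-fold, and the crotonyl-CoA hydratase gene Echs1 fell 2.17-fold. Glycolysis and lactate had 6 and 4 of 23 (0.50), and was called higher without MS-275 replicate 1 (0.00485). In that list Ldha had 289 ± 162 CPM with MS-275 and 306 ± 1.1 with DMSO (edgeR adjusted p = 0.766); its log2 fold change was 0.40 without MS-275 replicate 1 and −0.81 without replicate 2.

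In all, 11256 genes were called between MS-275 and DMSO by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5677 higher and 5579 lower. With at least a 2-fold change, 3384 were higher and 1075 lower, a ratio of 3.15. The groups did not overlap for 81.5% of genes (33.3% by chance). Adjusted over the list alone, rises and falls were 16 and 8 for neuron, 6 and 3 for glycolysis and lactate, 4 and 17 for mitosis, 3 and 15 for Notch pathway and 21 and 7 for synapse and ion channel, and unchanged for the other lists. Of 66 list tests in the 3 comparisons, 39 were called, and 5 with an estimated correlation: 3 at day 4, 2 at day 8 and 0 with MS-275, where 16 were called with the preset correlation.

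**Figure D2:**
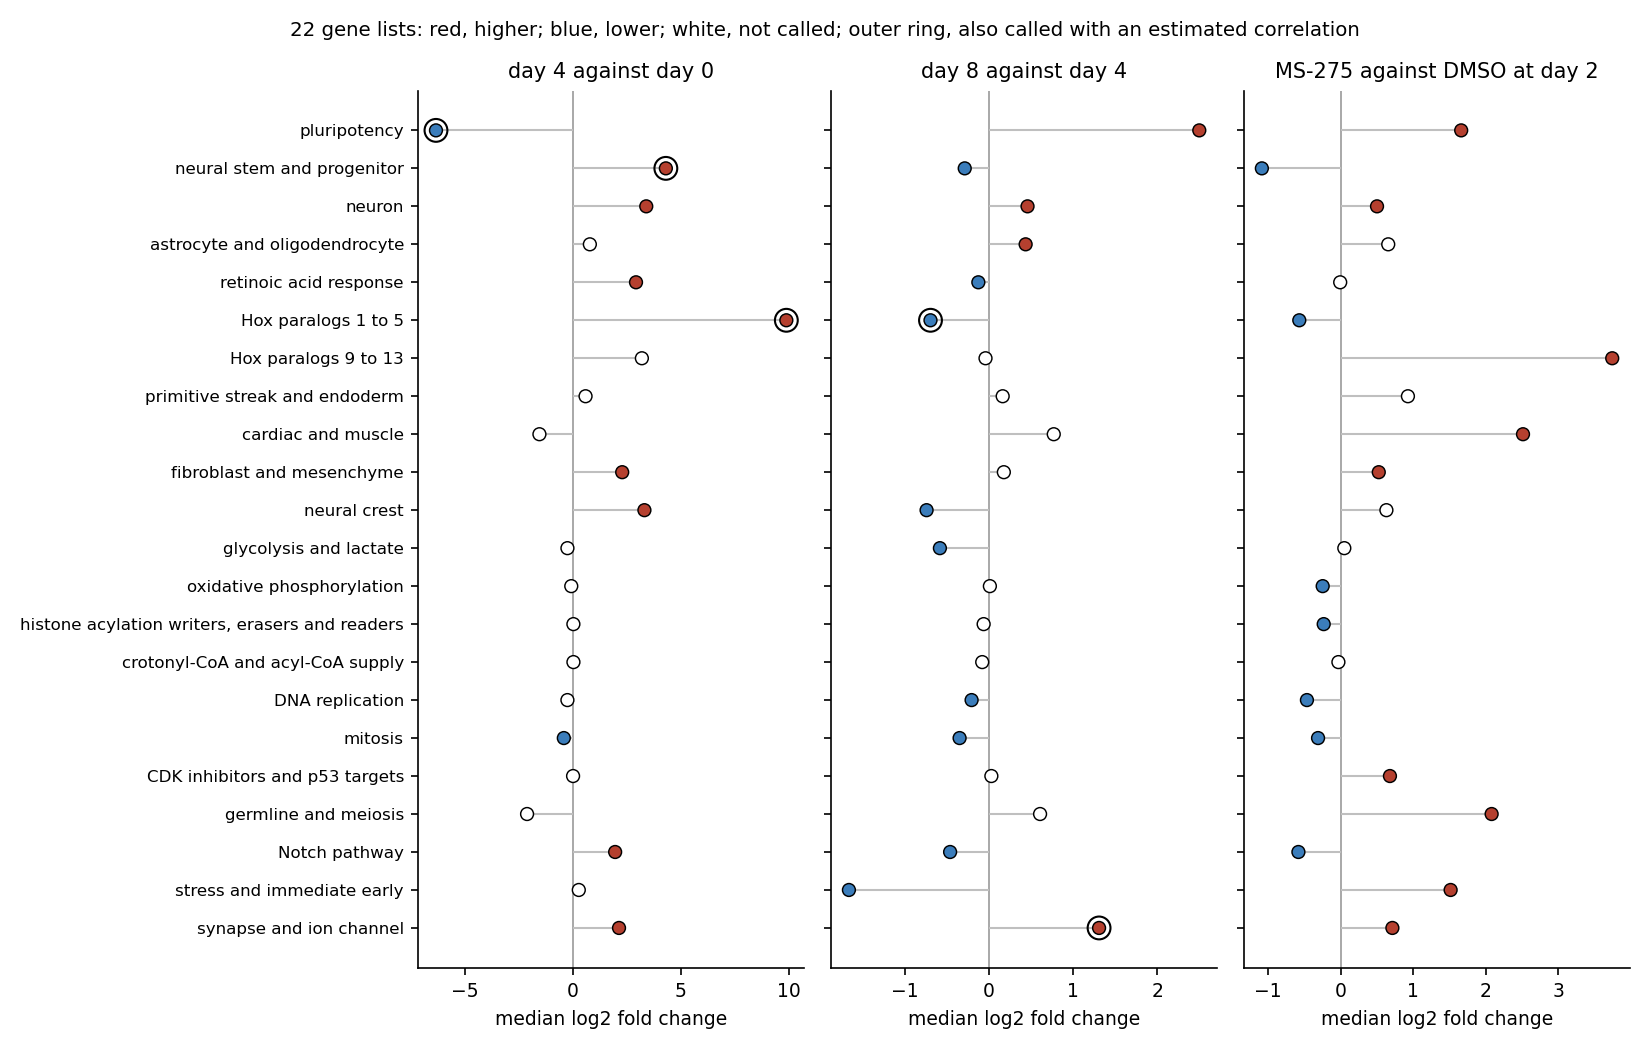
Each point is 1 of 22 gene lists in 1 of the 3 comparisons, placed at the median log2 fold change of its tested genes with genes at 0 counts set to their bound; red and blue mark lists called higher and lower by camera, white marks lists not called, and an outer ring marks a call that held with an estimated correlation. Hox paralogs 1 to 5 stood at 9.89 at day 4, −0.69 at day 8 and −0.57 with MS-275.

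The drug was also compared with differentiation itself, through genes that changed at least 2-fold between days in other libraries. The 3229 genes that fell from day 0 to day 4 were higher with MS-275 than with DMSO (median log2 0.79, 1745 up and 565 down, camera adjusted p = 6.03e-09; 0.00132 with an estimated correlation). The 1646 genes that rose from day 4 to day 8 were higher too (median 1.17, 957 up and 160 down, adjusted p = 2.86e-11; 0.00301 with an estimated correlation). The 3681 genes that rose from day 0 to day 4 split into 1148 up and 1098 down (median 0.01, the test pointing down, adjusted p = 0.923). The 657 genes that fell from day 4 to day 8 had a median of 0.37 (adjusted p = 0.0454), a call lost without DMSO replicate 1 (0.0855), DMSO replicate 2 (0.0615) or MS-275 replicate 2 (0.0773), and held with an estimated correlation (0.00301). These sets were lower with DMSO than other genes (medians of 1.39 to 4.54 CPM), and low genes tended to rise with the drug. With the change of other genes at the same DMSO level taken off, chosen after seeing the data, genes that fell to day 4 were still higher (0.50, adjusted p = 0.000117), as were genes that rose to day 8 (0.57, adjusted p = 0.000987). Genes that rose to day 4 were then lower (−0.27, adjusted p = 0.0192), and genes that fell to day 8 were not called (−0.05, adjusted p = 0.571).

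At day 4, the 3 histone marks and open chromatin were mapped to ask where crotonylation and lactylation lie relative to acetylation. H3K9cr lay almost entirely within H3K9ac: 99.4% of 27020 reproducible H3K9cr regions overlapped H3K9ac, against 3.62% for random placement, and 71.5% of 34801 H3K9ac regions overlapped H3K9cr. H3K18la reached further out, with 67.5% of its 42586 regions in H3K9ac and 53.6% in H3K9cr (3.21% and 2.41% at random). This depended on the threshold: with a −log10 q-value of at least 10, 88.1% of H3K18la regions lay in H3K9ac. The share of H3K9ac regions in H3K18la then went from 69.5% to 47.8%. Near gene ends lay 39.6% of H3K9ac, 50.2% of H3K9cr, 29.99% of H3K18la and 51.1% of ATAC regions, against 5.13%, 5.0%, 4.43% and 3.67% at random. Of 19164 ATAC regions, 82.4% overlapped H3K9ac, 76.7% H3K9cr and 58.8% H3K18la.

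Combined, the marks covered 47842 regions. All 3 marks shared 18788 of these (39.3%), of which 64.5% were open in ATAC and 54.2% lay near a gene end. H3K18la alone held 13825 regions (28.9%), of which 0.969% were open and 3.8% lay near a gene end. Random placement of all reproducible H3K18la regions gave 0.978% in ATAC and 4.43% near a gene end. Regions with H3K18la alone thus stood no higher than random placement in either. These combinations were not recounted with the stricter q-value, where most H3K18la regions lay in H3K9ac. H3K9ac with H3K9cr held 5756 regions, H3K9ac with H3K18la 4502 and H3K9ac alone 4822. The peak with the highest authors' fold enrichment for H3K9ac in replicate 1 (313) lay at ends of Hoxb3 and Hoxb9. Marks were present at the ends of 28 (H3K9ac), 28 (H3K9cr) and 26 (H3K18la) of 29 neural stem and progenitor genes and at 14, 13 and 8 of 28 pluripotency genes. Replicate lists overlapped by 88.7% ± 2.29 for H3K9ac, 90.2% ± 1.00 for H3K9cr, 73.4% ± 2.06 for H3K18la and 71.9% ± 8.28 for ATAC (SD over the 2 directions, n = 2), with Jaccard indices of 0.817, 0.822, 0.568 and 0.486. Overlap of peaks does not show that marks share a nucleosome or an allele.

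RNA levels at day 4 were higher for genes with more marks at their ends. Median levels in replicates 1 and 2 were 0 and 0 CPM for 7694 genes with no mark, 0.262 and 0.278 for 411 genes with 1 mark, 3.99 and 3.78 for 2445 genes with 2 marks, and 38.3 and 38.5 for 10379 genes with all 3. Genes with H3K9ac and H3K9cr but no H3K18la stood at 4.4 ± 0.0913 CPM (n = 2312 genes, SD over 2 libraries), and genes with all 3 at 38.4 ± 0.200. The distance between 2 and 3 marks depended on the threshold. With a −log10 q-value of at least 10, medians in replicates 1 and 2 were 16.2 and 16.2 CPM for 5584 genes with any 2 marks. They were 47.8 and 47.7 for 6828 genes with all 3. Across genes, the authors' fold enrichment at gene ends correlated with CPM, with Spearman values in replicates 1 and 2 of 0.80 and 0.803 for H3K9ac, 0.801 and 0.801 for H3K9cr, 0.695 and 0.712 for H3K18la and 0.646 and 0.636 for ATAC. Among genes with a peak these were 0.604 and 0.612, 0.603 and 0.599, 0.322 and 0.332, and 0.119 and 0.0888. These 16 relations are across genes, which are not independent replicates.

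Genes that changed carried day 4 marks more often than tested genes that were not called, in most of 16 tests by Fisher's exact test. H3K9ac marked 90.2% of genes that rose to day 4 and 79.4% of uncalled genes (odds ratio 2.39, adjusted p = 5.61e-44), and H3K18la 77.3% and 62.5% (2.05, adjusted p = 6.21e-49). H3K18la marked 82.3% of genes that fell after day 4 and 68.5% of uncalled genes (2.14, adjusted p = 1.13e-50). It marked 65.9% of genes that rose after day 4 (0.890, adjusted p = 0.00730; odds ratio 0.944, adjusted p = 0.219 without ChIP replicate 2), and open chromatin 63.0% against 66.6% (0.851, adjusted p = 0.000148; 0.980, adjusted p = 0.651 without replicate 2). Within deciles of day 4 expression, 9 of the 16 odds ratios crossed 1. Each set is defined by a change to or from day 4, so the day 4 level enters both the set and the deciles. The deciles therefore cannot tell whether expression level accounts for the marks. Of the 9 that crossed 1, 4 were called the other way by the Mantel-Haenszel test. One was open chromatin in genes that rose to day 4 (0.714, adjusted p = 2.51e-08). The others, in genes that fell after day 4, were open chromatin (0.713, adjusted p = 2.51e-08), H3K9ac (0.791, adjusted p = 0.0104) and H3K9cr (0.827, adjusted p = 0.0318). By the same test 6 of the 16 kept their direction and call. In genes that rose after day 4 these were H3K18la (0.806, adjusted p = 4.24e-05), open chromatin (0.765, adjusted p = 3.23e-08), H3K9ac (1.23, adjusted p = 0.00246) and H3K9cr (1.22, adjusted p = 0.00261). In genes that fell to day 4 they were H3K9ac (1.36) and H3K9cr (1.35, adjusted p = 9.35e-06 for each).

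**Figure D3:**
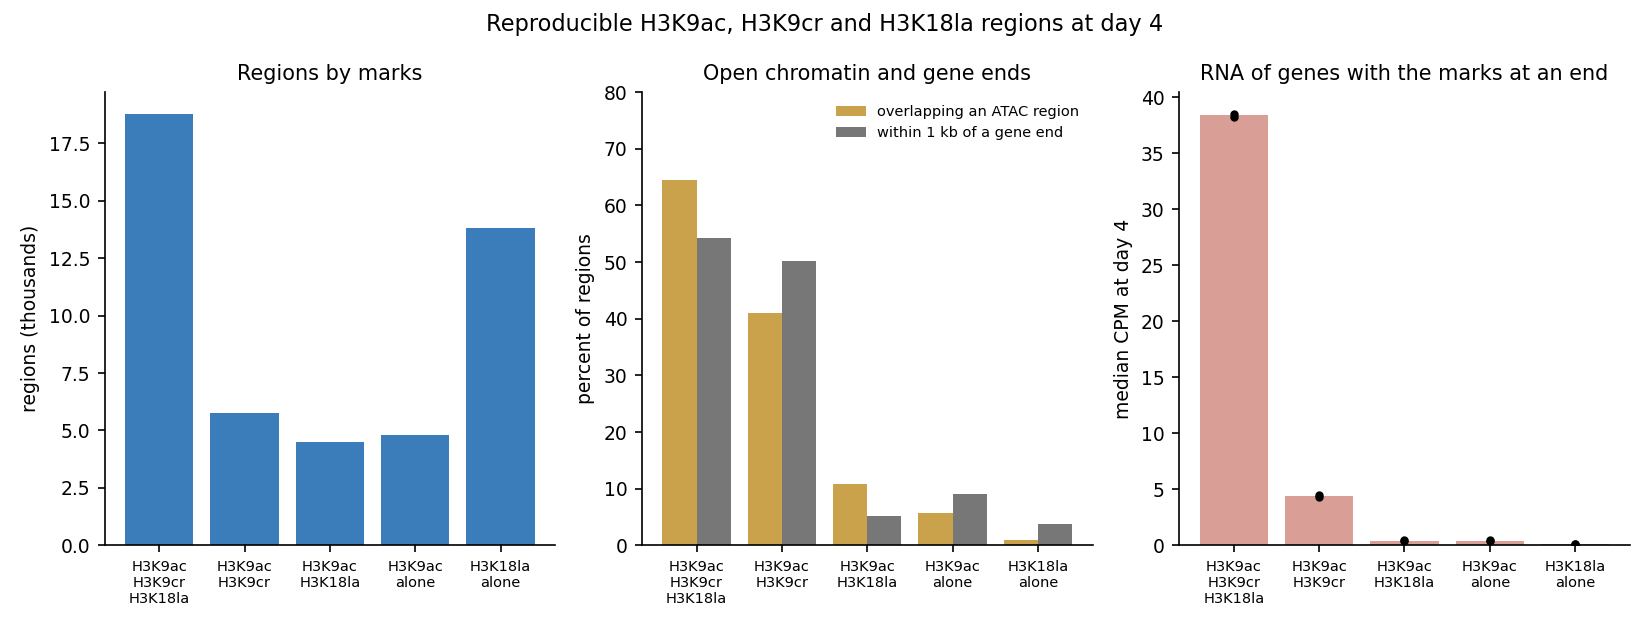
The panels show, at day 4, the number of regions by combination of marks, the percent of each combination that overlaps ATAC or lies within 1 kb of a gene end, and the median CPM of genes by combination at their ends, with points for the 2 RNA libraries. Regions with all 3 marks were open in 64.5% of cases and those with H3K18la alone in 0.969%. Random placement of all H3K18la regions gave 0.978%. Genes with all 3 marks stood at 38.4 CPM.

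The last comparison asked how MS-275 changed the marks at day 2, with 1 library per mark and condition and so no replicate check and no test. H3K9ac peaks numbered 26555 with DMSO and 84418 with MS-275 (3.18 times), covering 34.2 and 122 Mb. H3K9cr peaks numbered 24874 and 70748 (2.84 times), covering 32.5 and 107 Mb. H3K18la went the other way, from 36382 to 31577 peaks (0.868 times) and from 26.8 to 16.3 Mb. With a −log10 q-value of at least 10 the ratios of peak number were 1.77, 1.62 and 0.111. With MS-275, 70.6% of H3K9ac peaks, 66.0% of H3K9cr peaks and 59.7% of H3K18la peaks had no counterpart with DMSO, and 7.14%, 8.01% and 7.47% of these gained peaks lay near a gene end. Of the DMSO peaks, 3.65% of H3K9ac, 4.64% of H3K9cr and 69.3% of H3K18la had none with MS-275. These shares depended on list length: with lists of equal length 22.6%, 20.9% and 62.2% of MS-275 peaks were gained and 17.7%, 18.9% and 67.5% of DMSO peaks were lost.

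Genes with a peak at an end went from 12997 to 14652 for H3K9ac, from 12965 to 14418 for H3K9cr and from 11353 to 4867 for H3K18la. Cdkn1a (chromosome 17, 29090979 to 29100722) and Mapt had no H3K9ac or H3K9cr peak at an end with DMSO and both with MS-275. Hoxa9, Hoxc9 and Padi2 gained both and H3K18la as well. Among 16 Hox paralogs 9 to 13, H3K9ac and H3K9cr marked 7 with DMSO and 16 with MS-275, and H3K18la 2 and 9. Among 18 cardiac and muscle genes, H3K9ac marked 5 and 14. Mitosis genes kept H3K9ac at all 24 and went from 21 to 7 for H3K18la, and DNA replication genes from 24 to 8 of 25. Peaks were called per library with settings not given in the sources used here, so their number reads depth and enrichment of each library as well as the mark.

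**Figure D4:**
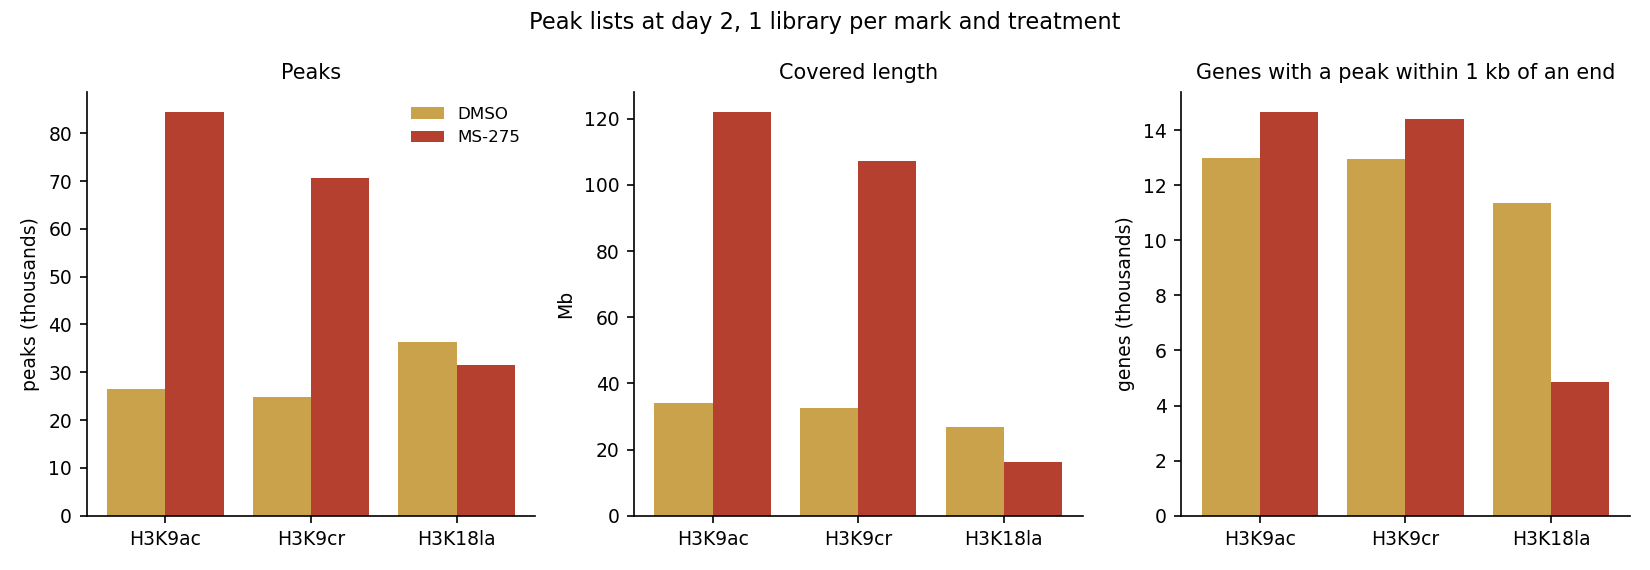
Bars give the number of peaks, the covered length in Mb and the number of genes with a peak within 1 kb of an end, for 1 library per mark with DMSO and 1 with MS-275. H3K9ac went from 26555 to 84418 peaks and H3K18la from 11353 to 4867 marked genes.

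Tested genes that gained a mark at an end had higher RNA with the drug, but they were low with DMSO (median 0.585 CPM for H3K9ac, 0.625 for H3K9cr and 0.850 for H3K18la). In all, 1726 genes gained H3K9ac, 1568 H3K9cr and 512 H3K18la, of which 1025, 953 and 397 were tested. The others were absent from the RNA table or did not pass the filter on low counts, so their RNA change is not covered. Sets that lost a mark were likewise limited to tested genes. Of all tested genes under 1 CPM with DMSO, 43.9% rose at least 2-fold. With the change of other genes at the same DMSO level taken off, an analysis chosen after seeing the data, the gained sets were still higher, by a median log2 of 0.57 (camera adjusted p = 0.0132), 0.63 (0.00764) and 1.14 (1.02e-06). They were also higher against genes of the same DMSO range (adjusted p = 1.20e-07, 8.94e-08 and 1.49e-12), a range that reached 93.9, 86.9 and 93.5 CPM. The 1025 tested genes that gained H3K9ac had a median log2 change of 1.61, with 595 up and 116 down (camera adjusted p = 1.13e-08; 0.00255 with an estimated correlation), and the 953 that gained H3K9cr 1.65, with 569 up and 110 down (adjusted p = 3.93e-09; 0.00255). The 397 that gained H3K18la had a median of 2.08, with 283 up and 36 down (adjusted p = 3.05e-13; 0.00340). The 6580 genes that lost H3K18la had a median of −0.13, with 1769 up and 2826 down (adjusted p = 0.00123; 0.000520), a call lost with the level taken off (−0.02, adjusted p = 0.462). The 47 genes that lost H3K9ac (median 0.01, the test pointing down, adjusted p = 0.640; −0.53, adjusted p = 0.0260 with the level taken off) and the 87 that lost H3K9cr (0.51, 0.115) were not called. Among gained genes with the highest authors' fold enrichment, the ion channel gene Trpv2 (H3K9ac) went from 0.157 ± 0.222 to 4.59 ± 0.332 CPM, while Pih1d1 (H3K9ac) fell 1.18-fold. Ppp1cc (H3K9cr) rose 1.44-fold, while Trim66 (H3K9cr) was not called. The RNA helicase gene Dhx58 (H3K18la) rose 7.46-fold, and Upk3b and Ido1 (H3K18la) were called higher too. Fscn2 gained H3K9ac and H3K9cr with RNA at 0.437 and 0.447 CPM. Among genes that lost H3K9ac, Paip1 fell 1.81-fold, Caps2 rose from 1.21 ± 0.430 to 2.98 ± 0.481 CPM and Pnp was not called. Among those that lost H3K9cr, Dync2h1 fell 2.39-fold and Naf1 1.27-fold, while Cnksr2 rose 1.41-fold. Fam234a (H3K18la) rose 1.51-fold, while Traf3 and Efhb (H3K18la) were not called.

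**Figure D5:**
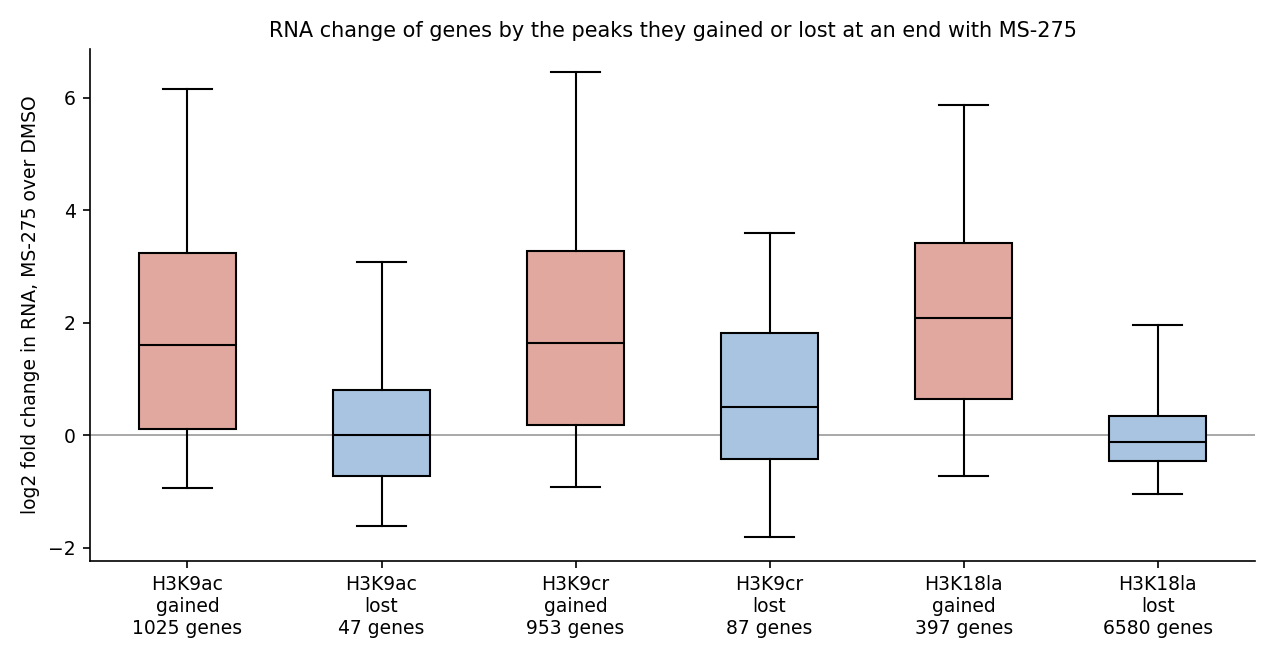
Box plots give the log2 RNA fold change between MS-275 and DMSO for tested genes that gained or lost a peak of each mark at an end, with boxes for the quartiles and whiskers from the 5th to the 95th percentile. Medians were 1.61, 1.65 and 2.08 for gained H3K9ac, H3K9cr and H3K18la and −0.13 for lost H3K18la.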

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

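No test in this part was chosen after the result was seen; the test of the H3K18la library was set before. The day 2 peak lists stood out because the number of peaks went in opposite directions between the marks. With MS-275 the number of peaks was 3.18 times that with DMSO for H3K9ac, 2.84 times for H3K9cr and 0.868 times for H3K18la. With a −log10 q-value of at least 10 these ratios were 1.77, 1.62 and 0.111, so the size of each depended on the threshold. The authors' fold enrichment did not part the marks: its median was lower with MS-275 in all 3 lists, 4.73 against 13.8 for H3K9ac, 5.02 against 16.7 for H3K9cr and 4.07 against 5.14 for H3K18la. Lists of different lengths hold different peaks, so the medians show no change at a given site. The maximum was lower with MS-275 too, 43.2 against 250 for H3K9ac, 53.2 against 279 for H3K9cr and 12.7 against 54.9 for H3K18la. Of the strongest 10% of DMSO peaks, 0 were lost for H3K9ac and 0 for H3K9cr. A longer list alone does not lower its maximum, so list length does not account for the lower maxima of these 2 marks. Each value came from 1 library per condition, and the difference between the marks was not tested.

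The smaller number of H3K18la peaks with MS-275 may come from a poorer H3K18la library rather than from less lactylation. Weak sites would then drop under the caller's threshold before strong ones, and this was seen: 32.9% of the strongest 10% of the DMSO peaks were lost (95% interval 31.4 to 34.4), against 79.1% of the weaker 50% (78.5 to 79.7). A real fall in H3K18la under deacetylase inhibition can also lower weak sites first and stays open, untested, because read depth and input were not analysed here and 1 library per condition was used.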

How the results depend on the processing

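The test with the change of genes at the same DMSO level taken off was chosen only after the results were seen; the others were set before. Where no cause is named, the cause was not tested. With 2 libraries per group, leaving 1 out assumes that the lone library varies like the other groups, and changes well under 1.5-fold and genes near the floor are at the limit of this depth.

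Counts of called genes moved by less than 1.5 times under every alternative except the 2-fold minimum, which by construction gave 6910 genes at day 4, 2303 at day 8 and 4459 with MS-275. Leaving out 1 library gave 11934 to 12043, 5872 to 6671 and 9890 to 10171 genes, and DESeq2 gave 11746 (genes changed day 4 against day 0), 5940 (genes changed day 8 against day 4) and 9764 (genes changed MS-275 against DMSO at day 2). The replicate numbers do not pair the samples: deviations of same-numbered libraries correlated by −0.0306 to 0.0378 over 10 pairs of groups. With the replicate block the counts were 12801, 7312 and 11182 and 39 lists were called; of named genes the block changed the call of Cdkn1c at day 8 (log2 −0.9986, adjusted p = 0.0468), and it changed no other call. An estimated correlation left 5 of 39 list calls. Over 462 alternatives for lists, 410 kept their call and direction, 44 lost the call, 1 gained it and 7 changed direction; over 2637 alternatives for the named genes reported these numbers were 2586, 36, 7 and 8.

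Every gene and list that changed direction had no call. Log2 changes at day 8 were, for Hdac3, −0.00083221 without a filter and −0.0124 to −0.0039 with a library left out; with a library left out they ranged from −0.0958 to 0.0252 for Pax6 and −0.0713 to 0.2032 for Tubb3. Ldha with MS-275 ranged from −0.8126 to 0.3963, and without MS-275 replicate 1 the rise was called. Lists that turned, with the range of adjusted p when 1 library was left out, were stress and immediate early at day 4 (0.913 to 0.995; turned at 0.976 without day 0 replicate 1 and 0.913 without day 4 replicate 2), crotonyl-CoA and acyl-CoA supply with MS-275 (0.761 to 0.998; turned at 0.998 without MS-275 replicate 1), retinoic acid response (0.885 to 0.974; turned at 0.935) and glycolysis and lactate (0.00485 to 0.496; turned at 0.103) with MS-275, both without MS-275 replicate 2, and oxidative phosphorylation at day 8 (0.0817 to 0.936; turned at 0.936 without day 4 replicate 2 and 0.474 without day 8 replicate 2). Genes that fell after day 4 had a median of 0.30 to 0.43 with MS-275 when 1 library was left out. With the change of genes at the same DMSO level taken off, they turned to −0.0454, genes that rose to day 4 were called lower (−0.2742), genes that lost H3K9ac were called lower (−0.5302), the test of genes that lost H3K9cr turned down (0.0179) and genes that lost H3K18la lost their call (−0.0212).

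For genes that lost H3K9ac, the test turned up with a window of 2.5 kb (median 0.37, adjusted p = 0.834) and with lists of equal length (0.28, 0.179), and was called lower against genes of the same expression range (−0.0886, 0.0270). For genes that lost H3K9cr it turned down against that range (0.51, 0.921). Within deciles of expression the odds ratios crossed 1 for genes that rose to day 4 (H3K9ac 0.979, H3K9cr 0.931, H3K18la 0.922, ATAC 0.714), for open chromatin in genes that fell to day 4 (0.943), and for genes that fell after day 4 (H3K9ac 0.791, H3K9cr 0.827, H3K18la 0.915, ATAC 0.713), and H3K18la in genes that fell to day 4 was no longer called (1.12); these genes differ from uncalled genes in expression. The day 4 level also enters the definition of these sets, so the deciles cannot show that expression level is the cause. With 1 ChIP replicate, odds ratios for genes that rose after day 4 were 0.857 to 0.944 for H3K18la and 0.901 to 0.980 for open chromatin. The median for genes without a mark was 0 CPM, so their distance to genes with 3 marks has no exact log2 value. With 1 CPM added to every gene, which sets its size, it was 5.30, and it was 5.21 with a window of 2.5 kb, 5.61 with the stricter q-value and 5.21 to 5.22 with 1 replicate.

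Overlaps moved under most alternatives, in both directions. Requiring 50% of a peak gave replicate overlaps of 85.4%, 87.4% and 64.0% for H3K9ac, H3K9cr and H3K18la, and a −log10 q-value of at least 10 gave 92.8%, 94.0% and 78.7%. With 50% overlap, the stricter q-value and a single replicate, H3K9ac lay in H3K9cr in 63.7%, 78.6% and 68.8% to 71.6% of cases, H3K9ac in H3K18la in 45.5%, 47.8% and 72.7% to 74.4%, H3K18la in H3K9ac in 57.4%, 88.1% and 60.1% to 61.5%, and H3K18la in H3K9cr in 44.1%, 75.6% and 46.3% to 49.6%. ATAC regions lay in H3K9ac in 76.3%, 93.6% and 72.9% to 75.7%, in H3K9cr in 69.0%, 90.9% and 65.3% to 69.9%, and in H3K18la in 41.5%, 52.6% and 57.2% to 62.0%. H3K9cr lay in H3K9ac in 99.7% with the stricter q-value and 98.4% to 98.8% with 1 replicate.

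For the day 2 lists (H3K9ac, H3K9cr and H3K18la), the stricter q-value gave ratios of peak number of 1.77, 1.62 and 0.111, gained shares of 44.98%, 39.3% and 45.02%, and lost shares of 5.42%, 7.17% and 94.2%. Lists of equal length gave gained shares of 22.6%, 20.9% and 62.2% and lost shares of 17.7%, 18.9% and 67.5%. Requiring 50% overlap gave 84.3%, 82.1% and 68.9% gained and 5.0%, 7.26% and 84.8% lost.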

Other observations

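The tests of day 0 cells and of total counts in this part were chosen only after the results were seen; those of thinned libraries and of receptor genes were set before. At day 2 with DMSO several genes stood outside the range between day 0 and day 4. Crabp2, which binds retinoic acid in the cytoplasm, had 970 ± 5.50 CPM at day 2 with DMSO (SD, n = 2), 25.9 ± 0.727 at day 0 and 78.9 ± 3.61 at day 4. Lefty1 had 193 ± 13.4 CPM at day 2, 168 ± 9.96 at day 0 and 1.89 ± 0.152 at day 4, while Pou5f1 lay between the days at 39.0 ± 1.38 CPM. The immediate early genes Fos and Egr1 had 0.878 ± 0.205 and 8.59 ± 0.964 CPM at day 2 with DMSO, against 70.7 ± 9.2 and 257 ± 9.49 at day 0 and 283 ± 21.0 and 870.2 ± 82.7 at day 4. Crabp2 and Egr1 were chosen after their values were seen, and no test was made between day 2 and the other days.

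The 2 MS-275 libraries differed widely in some genes of glycolysis and glucose uptake. Hk2 had 76.1 ± 64.2 CPM, Pfkfb3 31.9 ± 29.3, Pdk1 34.5 ± 25.9, Gpi1 679 ± 317 and Slc2a3 861 ± 322 with MS-275, where DMSO libraries gave 135 ± 11.9, 38.3 ± 2.12, 33.3 ± 1.94, 612 ± 19.6 and 442 ± 74.0. Pfkfb3, Pdk1 and Gpi1 were chosen after their values were seen. Of 4078 genes under 1 CPM with DMSO, 1789 rose at least 2-fold with MS-275 (43.9%) and 105 fell (2.57%), and of 2602 genes over 100 CPM 18 rose (0.692%) and 182 fell (6.99%). Low genes pass the expression filter through another group and have little room to fall, so this split favours rises at low levels. Of the 3384 genes that rose at least 2-fold, 809 (23.9%) were under 1 CPM on days 0, 4 and 8, as were 69 of the 1075 that fell (6.42%). In the day 2 lists, 83.2% of H3K18la peaks with MS-275 lay in H3K9ac, against 65.9% with DMSO (7.59% and 2.25% at random), while 21.3% of H3K9ac peaks lay in H3K18la, against 76.7%.

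Pluripotency genes were higher at day 8 than at day 4 in 15 cases, and cells that never left the day 0 state may account for part of this. A single share of unchanged day 0 cells would give every gene the same percent of its day 0 level. The 7 of these genes with at least 100 CPM at day 0 needed different shares, among them 24.0% for Lefty1, 7.98% for Lin28a (6.91% and 9.06% in single day 8 libraries), 2.76% for Pou5f1, 0.740% for L1td1 (0.563% and 0.918%) and 0.739% for Utf1. The second highest was 10.8 times the second lowest, which argues against such cells as the only cause. As a part of the cause they cannot be told apart from a rise in other cells, since bulk RNA does not show which cells express a gene. The 15 genes stood at a median of 8.56% of day 0, but some of them were low at day 0 or fell little. Genes with at least 20 CPM at day 0 that were at least 16-fold lower at day 4 were therefore compared. Among these, 11 pluripotency genes stood at a median of 2.94% of day 0 and the 90 other genes at 5.47%. By this median the pluripotency genes stood no higher than the other genes. More of them were called higher at day 8, 10 of 11 (90.9%) against 51 of 90 (56.7%). The sets share only the minimum fall, so the medians do not compare genes that fell equally far.

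Rises of at least 2-fold outnumbered falls 3.15 times with MS-275. Mean total counts with MS-275 were 0.999 times those with DMSO, and an MS-275 library had at most 1.041 times the total of a DMSO library, which argues against library size; thinning to the smallest total (3.09 times) had little to remove and decided nothing. Genomic DNA or other background reads may contribute: receptor genes of smell rose 1.57-fold in pooled CPM and other silent genes 1.72-fold, between the bounds set for this test. The bound set against background lay below no change in receptor genes, so this test could not have argued against background. Background therefore cannot be told apart from an effect of the drug. That effect stays open as well, and total RNA per cell was not measured.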
